A study of Mus musculus with 2 samples.

How the data were processed

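RNA was measured with 10x Visium in 2 fresh-frozen sections, 10 µm thick, of wild-type C57BL/6 mouse brain, labelled ZT12 and replicates 1 and 2. The deposited values are UMI counts per gene and spot over tissue, made by the authors with Space Ranger; the counts were whole numbers, with no normalization. Per the file headers section 1 was processed with Space Ranger 1.2.2 and section 2 with 2.0.1, while the submitters' processing notes name 2.0.1 and the mm10 genome for both, so any difference between versions is confounded with the section. The annotation release is not given in the sources used here. Spot positions were not used, so regions were defined from expression and no maps were drawn. Gene positions are those of RefSeq on GRCm38.p6.

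The files list 32285 genes. Spots with at least 500 UMIs were kept (3030 of 3167 in section 1 and 2531 of 2533 in section 2), and the dropped spots of section 1 had a median of 104 UMIs. Defining regions and testing them on the same genes would inflate the calls, so genes outside the fixed lists were divided at random. Of these, 15781 served to cluster and the other 16026, with 478 listed genes, were tested. Clustering used 2000 variable genes by Pearson residual variance, values scaled to equal totals, logged and centred per section, 30 principal components, a shared neighbour graph of 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, Python 3.11.15). It gave 22 clusters. The 14 with at least 30 spots in each section were tested, and 769 spots in the other 8 clusters were described only. No doublet caller was run, since a spot can hold several cells.

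Spots are not replicates, so counts were summed per section and region, which gave 28 sums. These were fitted with edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr (9398 held-out genes dropped), a term for the section, and quasi-likelihood F tests (13 residual and 21.62 prior degrees of freedom). Each region was compared with the mean of the other 13, and regions 18 with 8 and 6 with 2. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison, and counted as higher or lower when the change was also at least 2-fold. The SE of a log2 fold change is its size divided by the square root of F. All comparisons share sums, so they are not independent. Fold changes of a section alone come from that section's sums, with no test. A planned comparison of superficial with deep cortex was not run, because the cluster with superficial genes had 18 spots in section 2.

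Lists of cell type and function genes, written before the data were examined, were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over all 336 tests, and again with a correlation estimated for each list. Members were also adjusted over the list alone. Some lists share genes, so their results are not independent. For example, Slc17a7 is on the lists of synaptic vesicle genes and of vesicular glutamate transporters. The 18 lists of anatomical markers were described by the number of members higher in both sections and by their median, without a test. Of the 11 cell type and 15 function lists, 1 had under 3 measured genes and 1 served only to check the sex of the tissue, which left 24.

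The rule for naming genes was set before the data were examined. For each region it took the 10 largest rises and 5 largest falls among called genes with the same sign in both sections and an average log2 CPM of at least 5, for each pair of regions 10 in each direction, and for each list up to 4 called members. Genes without a symbol were counted and not named, and a few other genes are not reported here. Other listed genes named in the text, and the values per section singled out for Pmch, Oxt, Slc6a3, Arc and Hba-a1, were chosen after their values were seen.

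The steps were tested on simulated data. In spots drawn without any regions, 11 clusters still had enough spots to be tested, and the tests called 26 times over 7227 held-out genes (0.0327% of gene tests), against 99 times (0.136%) over the 6625 genes used for clustering. With 2-fold changes added to region 2, 91% were recovered, and 71% of 1.41-fold changes, with 6.90% of calls false. In region 9 these were 78%, 42% and 4%. In both regions camera called a list raised 1.41-fold and did not call a list of unchanged genes. The simulated genes were drawn independently in every step. The low share of calls over held-out genes therefore followed from the setting. It does not show how far calls are inflated in real held-out genes, which may vary with the genes used for clustering. Nor could the simulation show whether the preset correlation suits real lists, whose genes may be correlated.

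Alternatives set before the data were examined were DESeq2 1.42.0, no TMM factors, no filter on low counts, a filter of at least 10 counts in both sums of a region, no term for the section, no spot filter, clustering at resolutions 0.5 and 1.5, the other random division of genes, all sums thinned binomially to the smallest total (314169 UMIs), leaving out each section, an estimated correlation, and fry. Figures were drawn with matplotlib 3.10.9.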

Results

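Gene expression was measured with 10x Visium, an assay in which a tissue section lies on an array of barcoded spots and each spot records the RNA of a small area that can hold several cells. The samples were 2 sections of fresh-frozen wild-type C57BL/6 mouse brain, 10 µm thick, both labelled ZT12 (ZT commonly stands for zeitgeber time, counted from lights on). C57BL/6 is a widely used inbred strain. The stated purpose was to describe differences between brain regions, so every comparison below is between regions within these sections. Both sections form 1 group, labelled replicates 1 and 2 and called sections 1 and 2 here. The labels do not say that they came from separate animals, so p-values measure only how far regional differences varied between these 2 sections. That variation may be technical. It was pooled over all regions and drawn towards that of other genes, after a shift shared by all regions was removed. A gene can therefore be called in a region where the sections disagree.

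Section 1 had 3167 spots over tissue and 58662871 unique molecular identifiers (UMIs), and section 2 had 2533 spots and 55851559 UMIs. At least 500 UMIs were found in 3030 and 2531 spots, with medians of 18127 and 21555 UMIs and of 5419 and 5913 genes per spot. Mitochondrially encoded genes took 14.9% of the UMIs in section 1 and 14.3% in section 2.

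Joint clustering of the kept spots gave 22 clusters, of which 14 had at least 30 spots in each section and are called regions, by number and leading genes. They held 4792 spots, 85.2% of those kept in section 1 and 87.3% in section 2. The largest, region 1, held 605 spots of section 1 (exact binomial 95% CI of its share 18.6% to 21.4%) and 380 of section 2 (13.6% to 16.5%). These intervals treat spots as independent draws, so they do not measure variation between sections or animals. Several regions were unevenly represented. Region 5 held 10.5% and 2.33% of the spots, region 6 held 3.30% and 10.4%, and region 10 held 1.16% and 7.70%, in sections 1 and 2. The summed UMIs of a region in 1 section ran from 314169 (region 10, section 1) to 10079247 (region 1, section 1). The clusters came from genes that were then left out of the tests.

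Regional differences were widespread. Of 7106 tested genes, 4573 (64.4%) differed among the 14 regions by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. In the comparisons below, each region was set against the mean of the other 13, log2 fold changes are given ± SE from the fit of both sections (n = 2), and a gene is called higher or lower when it passed that test. Counts of genes refer to those that also changed at least 2-fold. Levels are given as CPM, counts scaled to the same total in every sum, and the leading gene of a region is the one with the largest rise among genes with an average log2 CPM of at least 5.

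**Figure D1:**
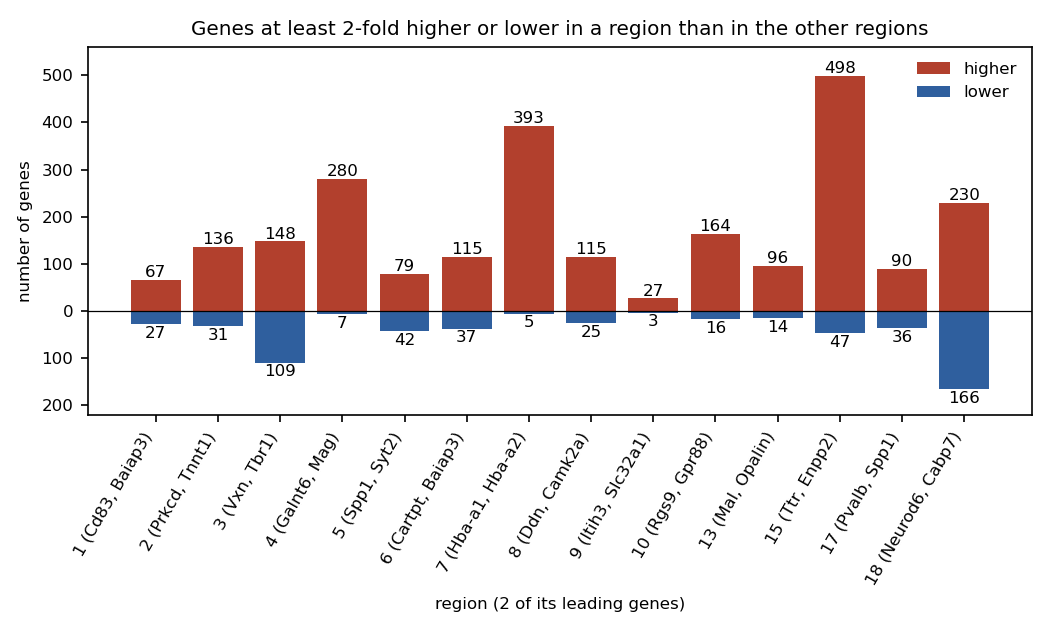
Number of tested genes (vertical axis) at least 2-fold higher (red) or lower (blue, drawn downwards) in each region than in the mean of the other regions, at an adjusted p under 0.05. Higher genes outnumbered lower genes in all 14 regions in this fit, from 27 against 3 in region 9 to 498 against 47 in region 15, but not under every alternative in regions 3 and 18.

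Region 3 (291 and 234 spots) was led by genes of deep cortical neurons. Vxn led, at 2.32 ± 0.07 on the log2 scale (chromosome 1, 9601267 to 9627142, GRCm38.p6), followed by Tbr1, a transcription factor of layer 6 neurons, at 2.25 ± 0.08 and Rprm at 1.82 ± 0.11. Of 9 measured deep isocortex markers, 8 were higher in both sections, with a median of 0.81. So were 4 of 5 markers of claustrum, endopiriform area and basolateral amygdala (median 0.60), so the region is not deep cortex alone by these lists. Cluster 12, with the superficial cortex marker Lamp5 at 316 and 193 CPM in sections 1 and 2, is outside the comparison. Stx1a stood at 244 and 320 CPM in cluster 12, against 187 and 182 CPM in region 3. The rises in region 3 therefore cannot be assigned to deep against superficial cortex. Genes induced by neuronal activity were also high in region 3. All 12 measured immediate early genes were higher (12 also adjusted over the list alone), among them Arc at 1.63 ± 0.08, Egr1 at 1.59 ± 0.11 and Nr4a1 at 1.42 ± 0.10 (camera adjusted p = 5.32e-15, adjusted p = 0.0744 with an estimated correlation). The level of Arc in this region was 151 CPM in section 1 and 70.9 CPM in section 2. Of 18 synaptic vesicle genes, 14 were higher and 2 lower (14 and 2 adjusted over the list alone), with the syntaxin gene Stx1a at 1.74 and the vesicular glutamate transporter Slc17a7 at 1.51 (camera adjusted p = 2.83e-16, adjusted p = 0.0357 with an estimated correlation). Of the 3 vesicular glutamate transporters, Slc17a7 was higher, Slc17a6 was lower at -0.75, and Slc17a8 did not pass at 0.77; the list stood above other genes (camera adjusted p = 0.00132, adjusted p = 0.0457 with an estimated correlation). Non-neuronal markers ran the other way. Of 12 astrocyte markers, 10 were lower and 1 higher (10 and 1 adjusted over the list alone), including the angiotensinogen gene Agt at -1.23 and Gfap at -0.95 (camera adjusted p = 2.77e-07, adjusted p = 0.0236 with an estimated correlation). All 5 red blood cell markers were lower (5 adjusted over the list alone; camera adjusted p = 0.0376, adjusted p = 0.483 with an estimated correlation). Microglial markers were lower for 9 of 11 (10 adjusted over the list alone; camera adjusted p = 0.000693, adjusted p = 0.247 with an estimated correlation) and endothelial markers for 8 of 10 (9 adjusted over the list alone; camera adjusted p = 0.000816, adjusted p = 0.183 with an estimated correlation). Mural cell markers were lower for 5 of 8 (7 adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.255 with an estimated correlation) and oligodendrocyte precursor markers for 4 of 6 (5 adjusted over the list alone; camera adjusted p = 0.0107, adjusted p = 0.213 with an estimated correlation). None of 12 fibre tract markers was higher in both sections (median -0.87). In total 148 genes were higher and 109 lower. The lower count was 40 in section 2 alone, and 35 without this region's own sum of section 1. Without that of section 2, 179 genes were higher and 221 lower, and with clustering at resolution 0.5 these were 169 and 177.

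Region 18 (31 and 38 spots) carried hippocampal pyramidal cell genes. Neurod6, a transcription factor of excitatory forebrain neurons, led at 3.52 ± 0.10 (chromosome 6, 55677818 to 55681263), with the calcium sensor gene Hpca at 2.52 ± 0.08 and the secretory granule gene Chgb at 2.40 ± 0.05. Of 8 measured markers of the hippocampal CA fields, 6 were higher in both sections, with a median of 2.17, among them Spink8 at 3.39, Nectin3 at 2.45 and Grik4 at 1.89; Wfs1 was lower at -0.87 and Mpped1 at -0.63, and Fibcd1 did not pass at 0.41. Of 18 synaptic vesicle genes, 13 were higher and 1 lower (14 and 2 adjusted over the list alone), led by Slc17a7 at 2.16 ± 0.06, Sv2b at 1.64 and Syn2 at 1.63 (camera adjusted p = 1.27e-26, adjusted p = 0.00636 with an estimated correlation). Of the vesicular glutamate transporters, Slc17a7 and Slc17a8 were higher and Slc17a6 lower (the same 2 and 1 adjusted over the list alone; camera adjusted p = 7.8e-09, adjusted p = 0.00152 with an estimated correlation). Postsynaptic density genes were higher for 10 of 13 (12 adjusted over the list alone), with the kinase gene Camk2a at 1.45 and the calmodulin-binding gene Nrgn at 1.37 (camera adjusted p = 8.7e-13, adjusted p = 0.0546 with an estimated correlation). Glycolysis genes were higher for 13 of 16 and lower for 2 (14 and 2 adjusted over the list alone), with the phosphofructokinase gene Pfkl at 1.29 (camera adjusted p = 9.29e-08, adjusted p = 0.0771 with an estimated correlation). The heat shock gene Hspa1b was higher at 2.17 ± 0.37, at only 14.6 and 19.4 CPM; its list had 5 of 8 genes higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.00703, adjusted p = 0.0744 with an estimated correlation). Microglial markers were lower for 7 of 11 (8 adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.355 with an estimated correlation), and red blood cell markers for 3 of 5 (4 adjusted over the list alone; camera adjusted p = 0.0217, adjusted p = 0.457 with an estimated correlation). In total 230 genes were higher and 166 lower, against 152 and 82 without this region's own sum of section 1, and against 220 and 236 with the other random division of genes.

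Region 8 (122 and 123 spots) was led by genes of the dendritic and postsynaptic compartment. Ddn, which encodes dendrin, led at 1.90 ± 0.10 (chromosome 15, 98803782 to 98807925), followed by Camk2a at 1.77 ± 0.08 and the ephrin receptor gene Epha7 at 1.63 ± 0.11. All 6 dentate gyrus markers were higher in both sections, with a median of 2.80; they include the desmosome gene Dsp at 2.73 and the granule cell transcription factor Prox1 at 1.32. The CA field markers were higher in both sections for 7 of 8, so the region is not dentate alone by these lists. Of 13 postsynaptic density genes, 11 were higher (12 adjusted over the list alone), including Psd at 1.26 (camera adjusted p = 1.75e-39, adjusted p = 0.00152 with an estimated correlation). Of 22 glutamate receptor genes, 9 were higher and 1 lower (10 and 2 adjusted over the list alone), with Grm2 at 1.66, Gria1 at 1.02 and Gria2 at 0.81 (camera adjusted p = 4.46e-06, adjusted p = 0.038 with an estimated correlation). All 13 mitochondrially encoded oxidative phosphorylation genes were higher (13 adjusted over the list alone), with mt-Nd6 at 0.70 and mt-Co2 at 0.57 (camera adjusted p = 8.87e-07, adjusted p = 0.34 with an estimated correlation), while 9 of 32 nuclear-encoded ones were lower (10 adjusted over the list alone; camera adjusted p = 0.000688, adjusted p = 0.324 with an estimated correlation). Mitochondrial genes took 19.4% and 16.9% of this region's UMIs. In total 115 genes were higher and 25 lower. Without this region's own sum of section 1 the counts were 74 and 11, the lower count was 15 in section 2 alone, and it was 40 without the own sum of section 2.

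Setting region 18 directly against region 8 compares hippocampal regions with CA markers and with dentate and CA markers together. Region 8 was also led by dendritic and postsynaptic genes. Clusters 19 and 20, with high Dsp and high Spink8, had under 30 spots in a section and are outside the comparison. The differences below therefore cannot be assigned to CA fields against dentate gyrus alone. The heparan sulfate sulfotransferase gene Hs3st4 was higher in region 18 by 2.10 ± 0.16, with Chgb at 2.03 ± 0.09, Neurod6 at 1.93 ± 0.12 and the copine gene Cpne4 at 1.89 ± 0.16. The vesicle genes Sv2b (1.35 ± 0.13) and Syn2 (1.25 ± 0.10) were higher too. Lower in region 18 were Mpped1 (-1.58 ± 0.24) and Wfs1 (-1.57 ± 0.23), which are on the CA list, together with Fam163b (-1.52 ± 0.13) and the transcription factor gene Bcl11b (-1.23 ± 0.20). By edgeR, 81 genes were at least 2-fold higher in region 18 and 89 lower. That balance turned with DESeq2 (69 and 64), with no term for the section (65 and 44) and with thinned sums. It held without TMM factors and under either other filter on low counts.

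Region 2 (349 and 281 spots) was led by thalamic genes. Prkcd, which encodes protein kinase C delta, led at 3.39 ± 0.11 (chromosome 14, 30595353 to 30626414), at 1021 CPM in section 1 and 775 CPM in section 2 against 89.5 and 102 CPM in the other regions. Tnnt1 followed at 3.19 ± 0.11, Plekhg1 at 2.99 ± 0.10 and the netrin gene Ntng1 at 2.50 ± 0.09, and all 8 thalamus markers were higher in both sections (median 2.58). Of 16 voltage-gated potassium channel genes, 11 were higher and 1 lower (11 and 1 adjusted over the list alone), with Kcnc2 at 1.47 and Kcna4 at 0.97, against Kcnq5 at -0.79 (camera adjusted p = 2.8e-10, adjusted p = 0.00653 with an estimated correlation). Slc17a6 (1.61 ± 0.09) and Slc17a7 (0.43 ± 0.06) were higher among the 3 vesicular glutamate transporters (2 also adjusted over the list alone; camera adjusted p = 0.000327, adjusted p = 0.0268 with an estimated correlation). The extrasynaptic GABA-A receptor subunit genes Gabrd (1.89 ± 0.06) and Gabra4 (1.81 ± 0.09) were high, yet over the 14 measured subunits 3 were higher and 2 lower (3 and 4 adjusted over the list alone). That list's median was -0.08 and its mean 0.15, and camera placed it above other genes (adjusted p = 0.0414, adjusted p = 0.303 with an estimated correlation). Of 17 circadian clock genes, 7 were higher (8 adjusted over the list alone), led by Hlf at 1.10 ± 0.07 (camera adjusted p = 0.000294, adjusted p = 0.0764 with an estimated correlation). Markers of GABAergic neurons were lower for 8 of 10 (8 adjusted over the list alone), among them Slc32a1 at -1.15 ± 0.10 and Gad1 at -1.01 ± 0.10 (camera adjusted p = 2.74e-06, adjusted p = 0.0841 with an estimated correlation). Of 27 ribosomal protein genes, 22 were lower (26 adjusted over the list alone), by a median of -0.21 (camera adjusted p = 8e-08, adjusted p = 0.214 with an estimated correlation). In total 136 genes were higher and 31 lower. The lower count was 15 in section 2 alone, 13 without this region's own sum of section 1 and 65 without that of section 2.

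Region 6 (100 and 263 spots) had high levels of hypothalamus markers and of several neuropeptide genes. Cartpt, which encodes the CART prepropeptide, led at 2.72 ± 0.14 (chromosome 13, 99898483 to 99910179), with 3.74 in section 1 alone and 2.52 in section 2 alone. Its level was 64.6 CPM in section 1 and 191 CPM in section 2, against 6.96 and 34.1 CPM in the other regions. Baiap3 followed at 2.26 ± 0.10 and Zcchc12 at 1.81 ± 0.08, and all 5 measured hypothalamus markers were higher in both sections (median 2.26). Also higher in both sections were 4 of 5 markers of claustrum, endopiriform area and basolateral amygdala (median 0.27). Of 20 measured neuropeptide genes, 12 were higher and none lower (13 and 0 adjusted over the list alone), including Tac2 at 2.27 ± 0.19 and Gal at 2.26 ± 0.28 (camera adjusted p = 2.52e-15, adjusted p = 0.00112 with an estimated correlation). For 2 of these genes the call rested on section 1. Pmch, the melanin-concentrating hormone gene, fitted at 4.50 ± 0.17, stood at 355 CPM in region 6 of section 1 and at 0.27 CPM in section 2, and Oxt, the oxytocin gene, fitted at 3.79 ± 0.77, at 10.7 and 0.13 CPM. Their log2 fold changes in section 2 alone were 0.04 and -0.06. Of 14 GABA-A receptor subunit genes, 7 were higher and 1 lower (7 and 2 adjusted over the list alone), with Gabrq at 3.20 ± 0.26 and Gabre at 2.86 ± 0.37 (camera adjusted p = 0.000254, adjusted p = 0.101 with an estimated correlation). Potassium channel genes were lower for 8 of 16 and higher for 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00149, adjusted p = 0.123 with an estimated correlation). GABAergic markers were higher for 7 of 10 and lower for 1 (7 and 1 adjusted over the list alone; median 0.50, camera adjusted p = 0.0195, adjusted p = 0.375 with an estimated correlation), the lower one being the parvalbumin gene Pvalb at -1.19 ± 0.13. In total 115 genes were higher and 37 lower. The lower count was 15 in section 1 alone, 13 without this region's own sum of section 2 and 74 without that of section 1.

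Set against region 2, region 6 gave the contrast of hypothalamus-led with thalamus-led spots. Cartpt was higher in region 6 by 3.15 ± 0.23, Baiap3 by 2.59 ± 0.15 and the nitric oxide synthase gene Nos1 by 1.81 ± 0.14. Tac1, which encodes substance P, was higher by 1.95 ± 0.24, with 3.02 in section 1 alone and 1.28 in section 2 alone; for Cartpt these values were 3.74 and 2.93. Prkcd was lower in region 6 by -3.81 ± 0.21, Tnnt1 by -3.74 ± 0.22, Plekhg1 by -3.67 ± 0.19 and Gabrd by -2.49 ± 0.11. By edgeR, 205 genes were at least 2-fold higher in region 6 and 179 lower. Higher genes also outnumbered lower ones with DESeq2 (183 and 167). With no term for the section (147 and 154) and with thinned sums they did not. Pmch and Oxt were among the genes called higher, on section 1: their log2 fold changes were 5.08 and 4.13 there, against 0.37 and -1.25 in section 2.

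**Figure D2:**
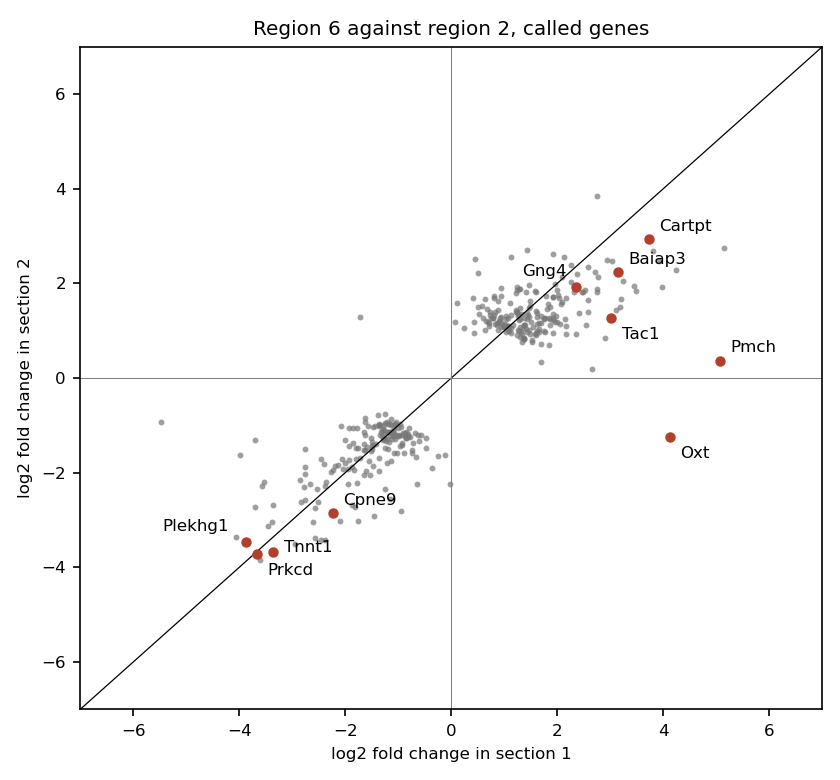
Log2 fold change of region 6 against region 2 in section 1 (horizontal axis) and in section 2 (vertical axis) for each gene called at least 2-fold different in the fit of both sections; the diagonal marks equal values. Prkcd, Tnnt1 and Plekhg1 lie near the diagonal, whereas Pmch (5.08 against 0.37) and Oxt (4.13 against -1.25) lie far from it.

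Region 10 (35 and 195 spots) was led by genes of striatal projection neurons. Rgs9, a regulator of dopamine receptor signalling, led at 3.66 ± 0.16 (chromosome 11, 109225348 to 109298181), with 4.87 in section 1 alone and 3.23 in section 2 alone. Its level was 390 CPM in section 1 and 369 CPM in section 2, against 16.1 and 40.4 CPM in the other regions. Penk (3.36 ± 0.12), Ppp1r1b (3.15 ± 0.12), which encodes DARPP-32, and Pde10a (2.92 ± 0.11) followed, and all 10 striatum markers were higher in both sections (median 3.27), including the dopamine receptor genes Drd1 at 3.39 and Drd2 at 3.11. Section 1 gave larger values for these receptors, 4.43 and 4.32, than section 2, 3.26 and 2.90. Markers of other tissue differed too: choroid plexus and ependymal lists had medians of 1.65 and 1.46 in the 35 spots of section 1, against -0.07 and -0.28 in section 2. Of 20 neuropeptide genes, 5 were higher and 1 lower (5 and 1 adjusted over the list alone), with Penk, Pdyn (3.13 ± 0.19) and Tac1 (2.58 ± 0.16) at the top. That list's median was -0.04 and its mean 0.53, and camera placed it above other genes (adjusted p = 5.73e-05, adjusted p = 0.0675 with an estimated correlation). The clock list had 7 of 17 genes higher (8 adjusted over the list alone), with Npas2 at 1.21 ± 0.22 (camera adjusted p = 0.00179, adjusted p = 0.218 with an estimated correlation). Astrocyte markers were lower for 8 of 12 (9 adjusted over the list alone; camera adjusted p = 0.00036, adjusted p = 0.101 with an estimated correlation). In total 164 genes were higher and 16 lower. Without this region's own sum of section 2, which leaves its 35 spots of section 1, the counts were 80 and 6, and in section 1 alone 8 genes were lower.

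Region 9 (106 and 130 spots) differed least from the rest, with 27 genes higher and 3 lower. No anatomical list was higher throughout: 7 of 10 striatum markers (median 0.55) and 3 of 5 hypothalamus markers (0.63) were higher in both sections. Its strongest group was cholinergic: all 3 measured genes were higher (3 adjusted over the list alone), the vesicular acetylcholine transporter gene Slc18a3 at 3.99 ± 0.37, the choline transporter gene Slc5a7 at 3.25 ± 0.31 and the acetylcholinesterase gene Ache at 0.89 ± 0.09 (camera adjusted p = 2.4e-32, adjusted p = 0.000139 with an estimated correlation). Slc18a3 stood at 44.4 CPM in section 1 and 27.3 CPM in section 2, against 1.66 and 4.78 CPM in the other regions. Of 10 GABAergic markers, 5 were higher (5 adjusted over the list alone), led by the transcription factor gene Lhx6 at 1.98 ± 0.19, with Slc32a1 at 0.98 ± 0.09 and Gad2 at 0.90 ± 0.10 (camera adjusted p = 2.19e-23, adjusted p = 0.00152 with an estimated correlation). Neuropeptide genes were higher for 4 of 20 and lower for 1 (5 and 1 adjusted over the list alone), with Tac2 at 2.36 ± 0.23 (camera adjusted p = 4.28e-05, adjusted p = 0.0546 with an estimated correlation). Slc17a7 was lower at -0.62 ± 0.08. The leading gene Itih3 was at 0.99 ± 0.17, but at 0.65 (edgeR adjusted p = 0.185) without this region's own sum of section 1. No gene was at least 2-fold lower without that sum, and 1 gene was lower without that of section 2.

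Region 17 (35 and 35 spots) was led by genes of fast-spiking inhibitory neurons. Pvalb led at 3.56 ± 0.09 (chromosome 15, 78191112 to 78206400), at 2871 and 2698 CPM against 310 and 231 CPM in the other regions. Ubash3b followed at 2.58 ± 0.16 and Lgi2 at 2.48 ± 0.11, and Spp1, the osteopontin gene, was at 2.98 ± 0.21, with 2.33 in section 1 alone and 3.47 in section 2 alone. Of 10 GABAergic markers, 4 were higher and none lower (5 and 0 adjusted over the list alone), namely Pvalb, Gad1 (2.44 ± 0.09), Gad2 (1.72 ± 0.12) and Slc32a1 (1.39 ± 0.10) (camera adjusted p = 5.91e-50, adjusted p = 0.000139 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were higher for 24 of 32 (27 adjusted over the list alone), with Cox5a at 0.63 ± 0.07 and Ndufb8 at 0.60 ± 0.07 (camera adjusted p = 8.99e-25, adjusted p = 0.00749 with an estimated correlation). Glycolysis genes were higher for 10 of 16 and lower for 1 (10 and 1 adjusted over the list alone), with Ldhb at 0.80 ± 0.06 (camera adjusted p = 3.54e-09, adjusted p = 0.0547 with an estimated correlation). Of the thalamus markers, 5 of 8 were higher in both sections (median 0.58), as were 8 of 12 fibre tract markers (median 0.21). In total 90 genes were higher and 36 lower, a split of 71.4% higher that was 86.5% (109 and 17) with DESeq2. The lower count was 15 without this region's own sum of section 1 and 10 without that of section 2.

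Region 5 (319 and 59 spots) shared high Spp1 and Pvalb. Spp1 was at 2.14 ± 0.14 (chromosome 5, 104435111 to 104441053), the synaptotagmin gene Syt2 at 2.10 ± 0.09, the neurofilament gene Nefh at 1.54 ± 0.08, Vamp1 at 1.54 ± 0.08 and Pvalb at 1.52 ± 0.09. Nuclear-encoded oxidative phosphorylation genes were higher for 29 of 32 (31 adjusted over the list alone), with a median of 0.29 and Cox5a at 0.59 ± 0.06 (camera adjusted p = 2.04e-22, adjusted p = 0.0204 with an estimated correlation), and glycolysis genes for 11 of 16 with 1 lower (11 and 2 adjusted over the list alone; camera adjusted p = 8.99e-08, adjusted p = 0.0807 with an estimated correlation). Postsynaptic density genes were lower for 10 of 13 (11 adjusted over the list alone), with Camk2a at -0.85 (camera adjusted p = 1.39e-07, adjusted p = 0.141 with an estimated correlation). Camera placed 2 lists above other genes whose medians were below 0. GABAergic markers had 4 higher and 3 lower (4 each adjusted over the list alone), a median of -0.16 and a mean of -0.09 (adjusted p = 0.0037, adjusted p = 0.261 with an estimated correlation), and potassium channels 5 higher and 3 lower (5 and 3 adjusted over the list alone), a median of -0.06 and a mean of 0.07 (adjusted p = 0.003, adjusted p = 0.101 with an estimated correlation). Midbrain markers had a median of 2.25, with 4 of 6 higher in both sections. The dopamine transporter gene Slc6a3, at 2.14 ± 0.19, stood at 33.0 CPM in section 1 and 2.48 CPM in section 2. In total 79 genes were higher and 42 lower, against 37 and 7 without this region's own sum of section 1, and 19 lower in section 2 alone.

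Region 1 (605 and 380 spots), the largest, was led by Cd83 at 1.19 ± 0.09 (chromosome 13, 43785112 to 43803133) and by the GABA transporter gene Slc6a11 at 1.11 ± 0.09, with Syt2 at 1.03 ± 0.09 and Slc17a6 at 0.97 ± 0.09. All 6 midbrain markers were higher in both sections, with a median of 2.30, among them Pax7 at 3.47 ± 0.41 and Gata3 at 3.07 ± 0.29, all at low levels (6.25 and 5.64 CPM for Pax7). All 5 measured hypothalamus markers (median 1.14) and 2 of 3 habenula markers were also higher in both sections, so the region is not midbrain alone by these lists. Monoamine neuron genes were higher for 5 of 7 (5 adjusted over the list alone), with Slc6a3 at 2.32 ± 0.16, the vesicular monoamine transporter gene Slc18a2 at 1.76 ± 0.22 and the tyrosine hydroxylase gene Th at 0.94 ± 0.17 (camera adjusted p = 6.05e-07, adjusted p = 0.00653 with an estimated correlation). Slc6a3 and Th are also on the midbrain list, so the monoamine result partly repeats that one. Slc6a3 stood at 33.4 CPM in section 1 and 7.52 CPM in section 2. Postsynaptic density genes were lower for 10 of 13 (12 adjusted over the list alone), with Ddn at -0.73 and Camk2a at -0.72 (camera adjusted p = 1.02e-10, adjusted p = 0.0764 with an estimated correlation). Immediate early genes were lower for 8 of 12 (9 adjusted over the list alone), with Arc at -0.69 (camera adjusted p = 0.000259, adjusted p = 0.318 with an estimated correlation). In total 67 genes were higher and 27 lower; the lower count was 11 in section 2 alone and 5 without this region's own sum of section 1.

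Region 4 (287 and 234 spots) was a myelin region. The glycosyltransferase gene Galnt6 was at 2.15 ± 0.11 (chromosome 15, 100689915 to 100729376), and the myelin genes Mag at 2.06 ± 0.10 and Mog at 1.94 ± 0.08. All 12 fibre tract markers were higher in both sections (median 1.87), as were 5 of 6 midbrain (0.60) and 5 of 7 ependymal markers (0.47). Glial lists rose with them. Astrocyte markers were higher for 7 of 12 (7 adjusted over the list alone), with Gfap at 1.69 ± 0.07 (camera adjusted p = 1.47e-05, adjusted p = 0.0457 with an estimated correlation). All 11 microglial markers were higher (11 adjusted over the list alone), with Ctss at 0.83 (camera adjusted p = 4.42e-07, adjusted p = 0.0807 with an estimated correlation), and 5 of 6 oligodendrocyte precursor markers (6 adjusted over the list alone), with Bcas1 at 1.61 (camera adjusted p = 0.000298, adjusted p = 0.0846 with an estimated correlation). All 5 red blood cell markers were higher (5 adjusted over the list alone; median 0.88, camera adjusted p = 0.0484, adjusted p = 0.51 with an estimated correlation), with Hba-a1 at 1.55 in section 1 alone and 0.47 in section 2 alone. Ribosomal protein genes were higher for 22 of 27 (24 adjusted over the list alone; median 0.26, camera adjusted p = 1.67e-06, adjusted p = 0.247 with an estimated correlation). Synaptic vesicle genes were lower for 15 of 18 (15 adjusted over the list alone; median -0.42, camera adjusted p = 2.93e-08, adjusted p = 0.116 with an estimated correlation). In total 280 genes were higher and 7 lower; the lower count was 3 in section 1 alone, 14 without this region's own sum of section 1 and 29 without that of section 2.

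Region 13 (56 and 52 spots) was also myelin-rich, at smaller sizes. Mal led, at 1.72 in section 1 alone and 1.26 in section 2 alone (chromosome 2, 127633226 to 127656695), with Opalin at 1.48 ± 0.14 in the fit of both and the oligodendrocyte transcription factor gene Sox10 at 1.32 ± 0.15, and all 12 fibre tract markers were higher in both sections (median 1.31). Cortical lists moved with them: 8 of 9 deep isocortex markers (median 0.49) and 4 of 5 markers of claustrum, endopiriform area and basolateral amygdala (median 0.62) were higher in both sections, and Slc17a7 was higher at 0.67 ± 0.07. Glycolysis genes were lower for 10 of 16 (11 adjusted over the list alone), with Ldhb at -0.48 ± 0.07 and Eno2 at -0.42 ± 0.07 (camera adjusted p = 1.02e-10, adjusted p = 0.0457 with an estimated correlation). Ribosomal protein genes were higher for 19 of 27 (22 adjusted over the list alone; median 0.26, camera adjusted p = 1.36e-17, adjusted p = 0.0547 with an estimated correlation). In total 96 genes were higher and 14 lower.

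Region 15 (46 and 57 spots) was led by choroid plexus and ependymal genes. In the fit of both sections it had the most higher genes of the regions, 498, with 47 lower. Ttr, which encodes the thyroxine carrier transthyretin, led at 5.51 ± 0.12 (chromosome 18, 20664209 to 20674326), at 73998 and 69596 CPM against 1837 and 1566 CPM in the other regions. Enpp2, the autotaxin gene, was at 4.08 ± 0.10. All 12 choroid plexus markers were higher in both sections (median 5.12), with the folate receptor gene Folr1 at 5.54 ± 0.14 and Kl, the klotho gene, at 5.30 ± 0.17. All 7 measured ependymal and tanycyte markers were higher too (median 4.84), with Tmem212 at 5.74 ± 0.33 and the ciliogenesis transcription factor gene Foxj1 at 3.39 ± 0.17. Markers of other tissue moved with them: 4 of 5 septum (median 1.63), 7 of 10 meningeal (1.04), 11 of 12 fibre tract (0.61) and 6 of 10 striatum markers (0.57) were higher in both sections. Synaptic vesicle genes were lower for 17 of 18 (17 adjusted over the list alone), with Cplx1 at -0.81 ± 0.08 and Syn2 at -0.80 (camera adjusted p = 2.29e-14, adjusted p = 0.0435 with an estimated correlation), and potassium channel genes for 9 of 16 (10 adjusted over the list alone; camera adjusted p = 0.000227, adjusted p = 0.0764 with an estimated correlation). The lower count was 87 without this region's own sum of section 2. Ttr had at least 1 UMI in all 2537 and 2152 spots of the other regions, with medians of 23 and 28 UMIs per spot against 248 and 347 in region 15, so a low Ttr count does not mark a place.

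Region 7 (201 and 128 spots) was led by genes of blood, vessels and meninges. The red blood cell genes Hba-a1 (3.41 ± 0.16), Hba-a2 (3.30 ± 0.15), Hbb-bt (3.24 ± 0.14) and Hbb-bs (3.16 ± 0.16) led; each pair is near-identical in sequence, so the split of reads within a pair is uncertain. All 5 red blood cell markers were higher (5 adjusted over the list alone; camera adjusted p = 3e-31, adjusted p = 0.00152 with an estimated correlation), and blood RNA therefore moved with every group below. Ptgds, a prostaglandin synthase gene of the leptomeninges, was at 2.98 ± 0.10 (chromosome 2, 25466709 to 25470110), and Mgp at 2.96 ± 0.08. All 10 meningeal markers were higher in both sections (median 3.12), as were 3 of 3 habenula (1.32) and 4 of 6 midbrain markers (1.15). The same held for 5 of 7 ependymal (0.50), 4 of 5 septum (0.47) and 4 of 5 hypothalamus markers (0.34). The region is therefore mixed by these lists. Mural cell markers were higher for 5 of 8 (5 adjusted over the list alone), with the smooth muscle actin gene Acta2 at 2.91 ± 0.10 and Vtn at 2.22 ± 0.09 (camera adjusted p = 3.03e-21, adjusted p = 0.00152 with an estimated correlation). All 10 endothelial markers were higher (10 adjusted over the list alone), with the von Willebrand factor gene Vwf at 2.20 ± 0.15 (camera adjusted p = 1.21e-09, adjusted p = 0.0268 with an estimated correlation). Astrocyte markers were higher for 10 of 12 and lower for 1 (11 and 1 adjusted over the list alone), with Gfap at 2.59 ± 0.06 and the water channel gene Aqp4 at 1.80 ± 0.07 (camera adjusted p = 6.82e-24, adjusted p = 0.000683 with an estimated correlation). Synaptic vesicle genes were lower for 15 of 18 (15 adjusted over the list alone; median -0.34, camera adjusted p = 6.6e-08, adjusted p = 0.13 with an estimated correlation). In total 393 genes were higher and 5 lower. Without this region's own sum of section 1 the counts were 204 and 1, and 12 genes were lower without that of section 2; in sections 2 and 1 alone 1 and 2 genes were lower.

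**Figure D3:**
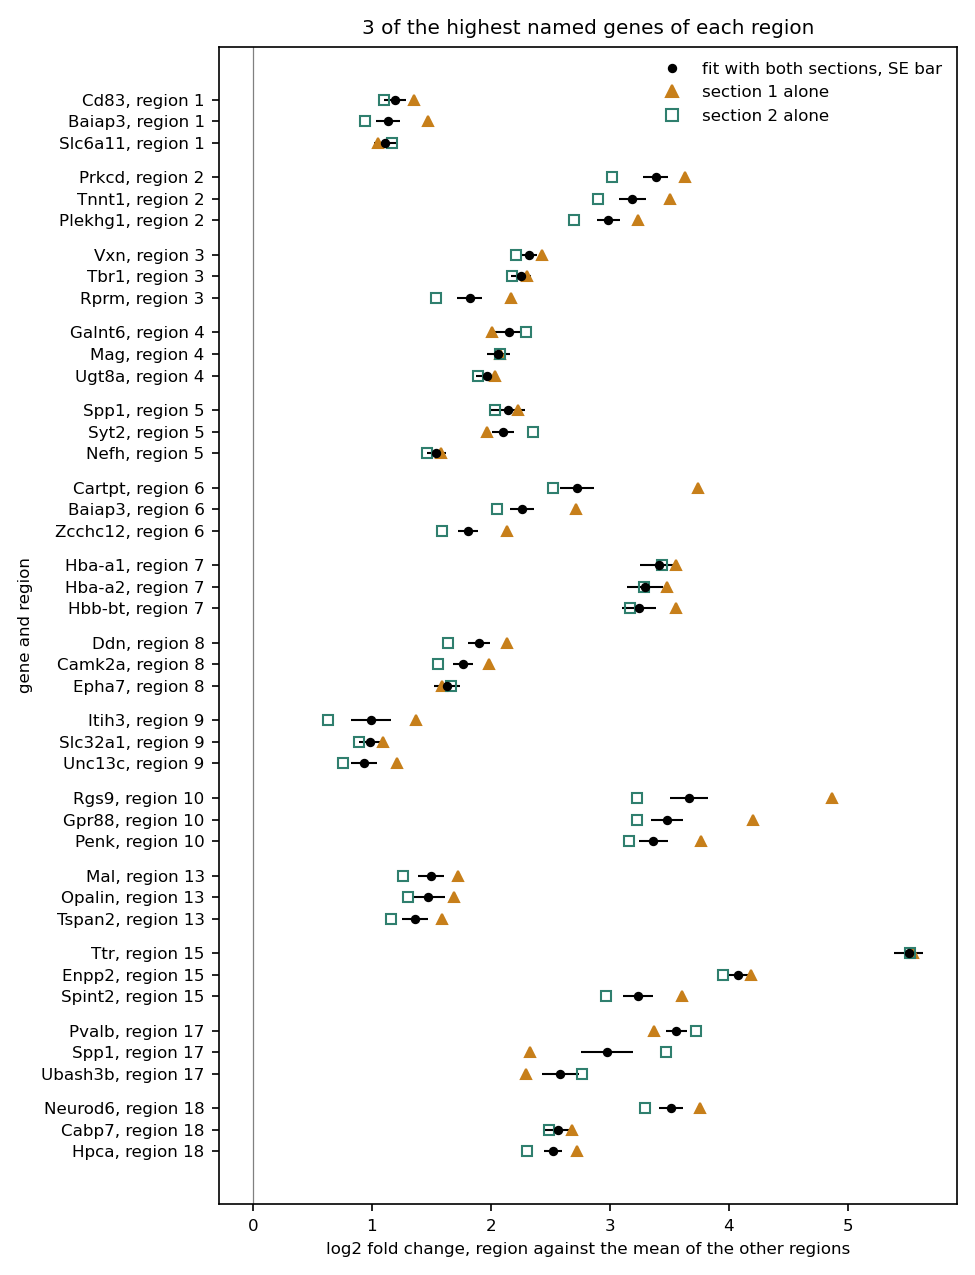
Log2 fold change (horizontal axis) of 3 of the highest named genes of each region (vertical axis) against the mean of the other regions; black points with bars are the fit of both sections ± SE, triangles are section 1 alone and squares section 2 alone. All 42 genes were higher in both sections, which the rule for naming genes required. Ttr in region 15 was the largest at 5.51, and Rgs9 in region 10 and Cartpt in region 6 showed the widest gaps between sections.

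Over all regions, 24 lists of cell type and function genes with at least 3 measured members gave 336 list tests, of which 148 passed at an adjusted p under 0.05 with camera's preset correlation of 0.01, 74 above and 74 below other genes. With a correlation estimated per list, 23 of the 148 calls held, 20 above and 3 below, and all 23 are given above with their p. With fry, which asks whether a list's genes move 1 way without comparing them with other genes, 138 of the 148 held.

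**Figure D4:**
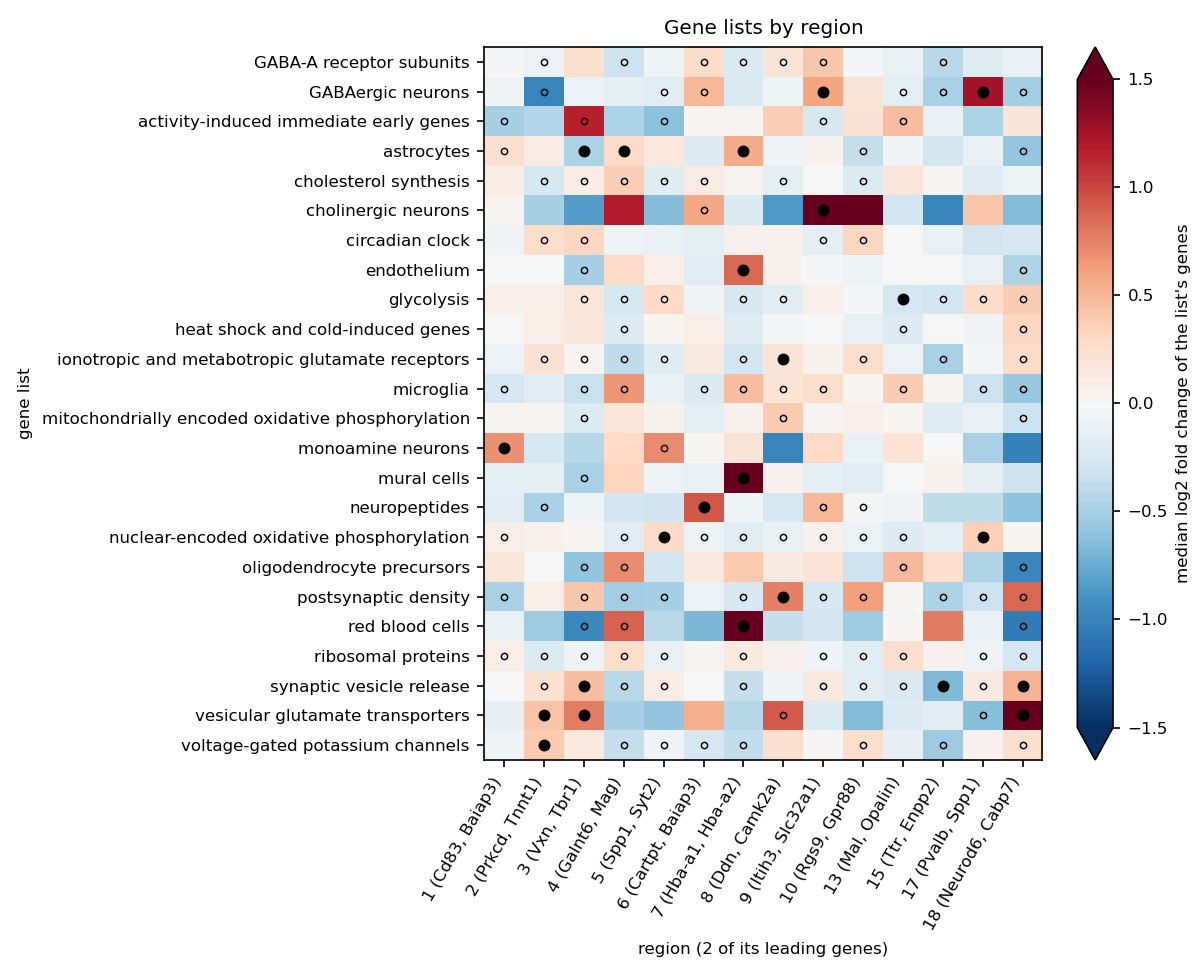
Median log2 fold change (colour, limited to 1.5 either side of 0) of each gene list (vertical axis) in each region against the mean of the other regions (horizontal axis). Open circles mark the 148 pairs called by camera and filled circles the 23 of them that held with an estimated correlation; the filled circles include cholinergic genes in region 9 and red blood cell, mural and astrocyte genes in region 7.

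How closely the sections matched varied by region. Across the 7106 genes, which are not independent replicates, Pearson's r between the sections' log2 fold changes ran from 0.14 in region 13 and 0.16 in region 9 to 0.676 in region 3, with a median of 0.417 over the regions; Spearman's rho was 0.251, 0.19 and 0.638 for those regions. Among genes with an average log2 CPM of at least 5, the median r was 0.772, from 0.407 in region 9 to 0.906 in region 2. Of the summed counts of each gene, the log2 CPM of the sections correlated at r = 0.981.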

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

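The tests in this part were set out before their results were seen, except the test of Ttr made by other regions' own cells, which was chosen after. The 8 clusters with under 30 spots in a section entered no comparison, so they are described here. For each, the gene given was picked as the one furthest above its mean level over the tested regions. Any cluster would hold such a gene, so its excess is a description only. Cluster 16, with 75 spots of section 1 and none of section 2, had Pcp2, a Purkinje cell gene, at 1702 CPM. Cluster 11 (25 and 190 spots in sections 1 and 2) had Trh at 52.9 and 105 CPM, and cluster 12 (177 and 18 spots) had Vip at 104 and 48.8 CPM. Cluster 14 (80 and 24 spots) had Rgs9 at 103 and 135 CPM, from 13 and 12 UMIs and below its 390 and 369 CPM in region 10. Cluster 19 (44 and 22 spots) had Dsp at 139.0 and 169 CPM, cluster 20 (25 and 25 spots) Spink8 at 169 and 141 CPM, and cluster 21 (21 and 22 spots) Nr4a2 at 140.2 and 86.9 CPM. Cluster 22, with 21 spots of section 2 and none of section 1, had Vgll3 at 68.1 CPM.

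Ttr was found in every spot of the other regions. Its level fell by 5.56 on the log2 scale from region 15 to the rest, and 5 other choroid plexus genes fell by a median of 4.97, a difference of -0.60. RNA from the choroid plexus reaching other spots may explain this, since the median stayed near that of Ttr, although Otx2 and Prlr fell by 3.66 and 3.65 only. Ttr made by the other regions' own cells would leave the choroid plexus genes scarcer relative to Ttr, and 0 of 13 regions had them over 1 log2 scarcer. How such RNA would reach the spots was not tested.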

How the results depend on the processing

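The tests that left out only a region's own sum of a section, and the rule that a cluster matching several regions stands for the closest one, were chosen after results were seen; in the former the lone sum is assumed to vary like the others. Without a whole section no spread is left, so those counts are genes of the fit of both sections also at least 2-fold changed in the remaining section, and genes that differ among regions have no such value. The cause of the changes below was not tested, except that thinning leaves fewer counts to test.

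The genes that differ among regions numbered 3222 to 4977 under every alternative but thinning, which gave 1814. DESeq2 gave lower genes of 2 in region 7, 1 in region 9, 8 in region 10, 8 in region 13, 23 in region 15 and 17 in region 17. Without TMM factors 20 genes were lower in region 4, 24 in region 6 and 3 in region 7. With no filter on low counts, 124, 214, 239, 124 and 178 genes were higher in regions 1, 2, 3, 5 and 6, and 12 lower in region 4. The filter of at least 10 counts left all these counts within 1.5 times. With no term for the section, 40 and 13 genes were higher in regions 1 and 9. Lower were 8, 15, 58, 4, 11, 16, 0, 11, 1, 9 and 9 in regions 1 to 10 and 13, in that order, and 44 in region 18 against 8. With no spot filter 54, 58, 13, 13 and 76 genes were lower in regions 2, 3, 4, 7 and 8. At resolution 0.5, 50, 54, 177, 21, 8 and 82 were lower in regions 1, 2, 3, 6, 7 and 8, and at resolution 1.5, 40 and 11 in regions 3 and 4. With the other division of genes 34, 44 and 24 were lower in regions 3, 4 and 6. Regions without a matching cluster numbered 4 at resolution 0.5, 3 with no spot filter, 1 with the other division and 0 at resolution 1.5.

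With thinned sums 13, 82, 67, 30, 42, 114, 59, 7, 194 and 143 genes were higher in regions 1, 2, 3, 5, 6, 7, 8, 9, 15 and 18. Lower were 5, 20, 47, 24, 12, 10, 3, 13, 0, 7 and 20 in regions 1 to 9, 13 and 17. Region 18 against 8 had 47 and 41, and region 6 against 2 had 73 and 96. Depth therefore limits most of these counts, though lower genes in region 4 rose from 7 to 24.

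Leaving out a section or a region's own sum gave these ranges. Higher genes were 37 to 83 in region 5, 204 to 443 in region 7, 74 to 121 in region 8, 80 to 161 in region 10 and 152 to 249 in region 18. Lower genes were 5 to 32 in region 1, 13 to 65 in region 2, 35 to 221 in region 3, 3 to 29 in region 4, 7 to 44 in region 5, 13 to 74 in region 6, 1 to 12 in region 7, 11 to 40 in region 8, 0 to 3 in region 9, 6 to 16 in region 10, 32 to 87 in region 15, 10 to 30 in region 17 and 82 to 180 in region 18.

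Of 250 results for named genes, 1 lost its call with DESeq2, 29 with no term for the section and 40 with thinned sums. Another 21 of 210 did so without the own sum of each section, 3 of 185 with no spot filter and 1 of 170 at resolution 0.5. None of 250 did without TMM factors, under either other filter on low counts or at resolution 1.5, and none of the 103 with a value under the other division of genes. Without a whole section no call could be lost, so this says nothing about stability. Cacna2d3 in region 7 changed sign with thinned sums, to 0.18 (edgeR adjusted p = 0.864). Of 148 list calls, 23 held with an estimated correlation, and 10, 5, 11 and 18 were lost with fry, without TMM factors, with no filter and with no term for the section. The median correlation of the sections was 0.507 and 0.456 at resolutions 0.5 and 1.5, and 0.772 for genes with an average log2 CPM of at least 5.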

Other observations

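The tests in this part were set out before their results were seen, except the comparison of region 9's anatomy lists with those of other regions, which was chosen after, and the patterns came from the same data. Both sections had Y-linked transcripts and almost no Xist: Ddx3y had 2411 and 2089 UMIs, Eif2s3y 1365 and 1555, and Xist 0 and 1. Several immediate early genes were lower in section 2, with Arc at 69.9 and 30.6 CPM and Fos at 30.6 and 12.7 CPM, while Npas4 had 705 and 780 UMIs. The clock genes Nr1d1 (59.2 and 80.4 CPM) and Dbp (150 and 171 CPM) were higher in section 2 in all 14 regions, Per1 in 7 of 14, Nr1d2 (122 and 109 CPM) in 4 and Per3 (32.9 and 25.2 CPM) in 1. In all, 378 of 7942 genes were higher in section 2 in all 14 regions and 280 lower. These are values of 1 section each, with no test.

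Of the genes compared, 15 were at least 2-fold higher in section 2 in all 14 regions, among them H1fx, Ppp1r14a, C1qtnf4, Pcsk1n and Grin1, and Cbln1 was at least 2-fold lower. As the whole cause for these genes as a set, different anatomy of the sections is argued against. In 6 clusters not used to choose the genes, the lowest median difference was 1.42 on the log2 scale in the same direction. The check cannot exclude RNA that reached those clusters from tissue present in 1 section only. Nor does it speak for Cbln1, a gene of the cerebellum list: cluster 16, led by cerebellar genes, had spots in section 1 only. Over the tested regions Pcp2 stood at 41.4 and 0.857 CPM and Gabra6 at 16.2 and 0.200 CPM in sections 1 and 2. Different anatomy therefore stays open for Cbln1. For reads shared with overlapping genes the odds ratio was 0.84 (Fisher exact p = 0.806, 95% CI 0.313 to 2.26), an interval that keeps this cause open. The Space Ranger version, the animal and GC content stay open and were not tested. Regional comparisons were made within sections, so a shift shared by all regions cancels in them.

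The regions differed in how closely their fold changes matched between sections. With all sums thinned to the same total, the highest and lowest correlations still lay 0.502 apart (0.615 in region 15, 0.113 in region 9), which argues against depth as the whole cause. Low counts were filtered again after thinning, so these values rest on other genes than the full sums. In region 10, for example, r rose from 0.252 to 0.414. Region 15 also had the most genes at least 2-fold higher, 498, and region 9 the fewest, 27. Whether r follows the size of the changes was not tested. Different anatomy joined in 1 cluster stays open. In region 9 the hypothalamus list had a median of 1.42 in section 1 and 0.33 in section 2, a difference of 1.09 over 5 genes, past a bound of 1 set beforehand. But 9 of 14 regions had a list past that bound, among them region 15, the best match, with 1.88 for midbrain markers, so the difference does not single out region 9. No biological explanation was tested.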
